A study of Mus musculus with 9 samples.

How the data were processed

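Single-cell RNA was measured in 9 mouse liver libraries, 3 in each of 3 groups: Brd4 fl/fl mice given olive oil, Brd4 fl/fl mice given CCl4, and Brd4 LSECKO mice given CCl4. Per the labels' protocols, Brd4 LSECKO mice carried floxed Brd4 alleles and a tamoxifen-inducible Cdh5-CreERT2 recombinase and received 75 mg/kg/day of tamoxifen for 5 days. The labels do not say whether the fl/fl mice received tamoxifen or carried the recombinase. The livers were perfused, hepatocytes were removed by a spin at 50 g, the remaining cells were pelleted at 300 g, and 10000 cells per library were the target for the 10x Genomics 3' version 3 chemistry. The labels do not say whether each library came from a separate animal, so the p-values here measure the spread between these libraries, which may be technical in part. The dose and duration of CCl4 are not given in the sources used here.

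The deposited values are raw UMI counts per gene and cell barcode, produced with Cell Ranger 7.2.0 per the file headers and the submitters' processing notes, with the barcodes already called as cells by the authors. The processing notes also list Seurat 5.1.0 with no role. The only genome build they list is hg38, which goes against the mouse Ensembl identifiers of all 32285 features in the files, so the build behind the counts is not given in the sources used here. Gene symbols and identifiers are those of the files, and the coordinates of 4 genes were looked up in GENCODE M21 (GRCm38).

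The files held 102894 barcodes. Barcodes with under 200 genes or over 20% mitochondrial UMIs were removed (6 to 32 per library), which left 102748. Doublets were scored per library with Scrublet in scanpy 1.11.5, on genes found in at least 3 cells. Its automatic threshold marked under 0.5% of barcodes in 2 libraries (CCl4 fl/fl 2 and Brd4 LSECKO 2) and was taken not to have worked there. In those the median threshold of the other 7 libraries (0.1431) was used. In all 7465 barcodes were called doublets and removed, leaving 95283 cells. Counts were scaled to 10000 UMIs per cell, logged, and reduced to 2000 variable genes and 40 principal components, and cells were joined to 15 neighbours and clustered by the Leiden method at resolution 1.0 (Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9).

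Of 39 clusters, 24 were named as cell-type-like from markers fixed before the data were examined. A name needed at least 3 markers among the 50 leading genes of the cluster (by fold, detected in at least 25% of its cells), at least 1 of its own among the 10 leading genes and no more of another class there. Another 15 clusters stayed unnamed, 10 of them because at least 25% of their barcodes were called doublets, judged in the 7 libraries where the automatic threshold worked. That rule was set after the data were seen. Doublet-rich unnamed clusters held 4.48% ± 1.12 (SD) of the cells in oil, 9.53% ± 12.8 in CCl4 fl/fl and 11.4% ± 15.5 in Brd4 LSECKO. The other unnamed clusters held 2.86% in oil, 11.9% in CCl4 fl/fl and 10.6% in Brd4 LSECKO on average. The names make 14 classes. The 12 classes with at least 20 cells in every library were tested, and mesothelial and plasma cells (7 cells in the smallest library) were not. Because genes that differ between groups also shape clusters, shares were computed again after clustering without the markers, the listed genes and the 10 leading genes of every cluster (433 of the 2000 variable genes left out, 1567 used), an alternative added after the data were seen.

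The UMI counts of each class were summed per library and tested with edgeR 4.0.16's quasi-likelihood test in R 4.3.3 (TMM scaling, filterByExpr, all 9 libraries in 1 fit with group means only), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The standard error of a log2 fold change was taken as its size over the square root of the F statistic. CPM values are the summed UMI counts of a class scaled to a common library total. Shares of cells were compared with a two-sided exact permutation test over libraries, whose smallest p is 0.1 for 3 against 3, adjusted over the 28 tests of 14 classes and both comparisons. In all 23 gene lists, fixed before the data were examined, gave 108 tests with camera on limma 3.58.1 voom values at its preset correlation of 0.01, adjusted within each class and comparison, and again with an estimated correlation and with fry. The overlap of the 2 comparisons, which share the CCl4 fl/fl libraries, was set beside 20 simulations of unchanged groups and beside the overlap of independent lists.

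The named genes follow a rule fixed before the data were examined. It takes Brd4, Pml, Cdh5 and Ccl2 in endothelial cells whatever their values, up to 4 members of each list past the threshold by smallest p, and, per direction, the 8 genes with the largest change among those at 20 CPM or more whose libraries do not overlap. From these the text prefers genes whose call held without each library in turn, a narrower choice made after the data were seen. The tests were checked on simulated counts with 200 changed genes. For 2-fold and 4-fold changes the quasi-likelihood test recovered 71.7% and 85.6% in endothelial cells (13244 genes), 35.7% and 83.5% in Kupffer cells (10034 genes), 51.0% and 92.8% in monocyte/macrophage cells (6808 genes) and 6.19% and 77.4% in stellate cells (9404 genes), so a 2-fold change was often not detectable in the smaller classes. Of all calls in these simulated counts 9.41%, 7.94%, 2.10% and 8.24% were of unchanged genes in the 4 classes, above the threshold of 0.05 in all but the monocyte/macrophage class.

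Pairs of libraries in a group were compared by a chi-square test of their counts, and none agreed within sampling noise. Groups share replicate numbers, so same-numbered libraries were checked for deviations from their group means that go together. Between CCl4 fl/fl and Brd4 LSECKO all 3 pairs correlated above 0.1 across genes in endothelial cells (0.137 to 0.419) and in stellate cells (0.231 to 0.611). The highest correlation between libraries of different numbers was 0.0418 in endothelial and 0.246 in stellate cells. Deviations from the mean of 3 libraries cancel out, so the 3 pairs are not independent. From the data and not from the labels, the numbers were taken to pair the libraries for those 2 classes in that comparison. These correlations do not settle it. The numbers were not taken to do so elsewhere (in Kupffer cells 2 of 3 pairs and in monocyte/macrophage cells 1 of 3). Between Brd4 LSECKO and oil the endothelial pairs were above 0.1 too (0.148, 0.258 and 0.124), as was oil 1 with Brd4 LSECKO 3 (0.123). Alternatives tried were DESeq2 1.42.0, DESeq2 size factors within edgeR, no filter on low counts, the replicate block, a fit of the 6 libraries of a comparison only, UMIs thinned to the smallest library, called doublets kept, at most 10% mitochondrial UMIs, at least 500 genes, Leiden resolution 0.5, another denominator for shares, edgeR on cell counts, and each library left out in turn. Added after the data were seen were the re-clustering, leaving out the 2 libraries richest in barcodes (CCl4 fl/fl 2 and Brd4 LSECKO 2), doublets by an expected rate that grows with the number of barcodes, doublet-rich clusters judged over all libraries, genes under 10% of their level in the highest class left out, and the comparison of Brd4 LSECKO with oil. Plots were drawn with matplotlib 3.10.9.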

Results

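Single-cell RNA-seq was used to follow the cells of the fibrotic liver when the transcriptional co-activator Brd4 is deleted in endothelial cells. Libraries were made from livers of Brd4 fl/fl mice given olive oil (the vehicle), Brd4 fl/fl mice given CCl4 (a hepatotoxin widely used to induce liver fibrosis) and Brd4 LSECKO mice given CCl4. Each group had n = 3 libraries. LSECKO stands for knockout in liver sinusoidal endothelial cells (LSECs), the fenestrated endothelium that lines the hepatic sinusoids. The series title places the work on endothelial PML, the scaffold protein of PML nuclear bodies, and on macrophage infiltration. The libraries held 30395156, 42371653 and 32618119 UMIs in oil, 47149795, 34968937 and 49477307 in CCl4 fl/fl, and 37242381, 51912567 and 35757768 in Brd4 LSECKO. The number of barcodes ran from 8063 to 19890 per library and the median UMIs per barcode from 1570 to 4136. CCl4 fl/fl 2 and Brd4 LSECKO 2 stood apart, with 16374 and 19890 barcodes at medians of 1570 and 1944.5 UMIs. After filtering, 95283 cells fell into 39 clusters, of which 24 made up 14 classes. The names stand for cells that carry the markers of that type (endothelial-like, Kupffer-like and so on), and are written without the suffix. Since hepatocytes were spun out before loading, shares of cells are those of the pellet, not of the liver.

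The targeted gene was examined first. Brd4 (ENSMUSG00000024002; chromosome 17, 32196274 to 32284722, minus strand, in GRCm38) was measured in endothelial cells at 174.07, 178.93 and 167.38 CPM in the oil libraries, 169.8, 190.24 and 162.29 CPM in CCl4 fl/fl, and 177.64, 152.55 and 184.39 CPM in Brd4 LSECKO. Its log2 fold change was 0.00 ± 0.11 (SE) for CCl4 against oil (adjusted p = 0.99) and -0.02 ± 0.11 for Brd4 LSECKO against CCl4 fl/fl (adjusted p = 0.94). The labels do not say which part of the gene is deleted, and a 3' tag outside that part checks nothing, so these values neither bear out nor contradict the genotype labels. Pml (ENSMUSG00000036986; chromosome 9, 58218076 to 58249786, minus strand) lay between 43.8 and 62.4 CPM over the 9 libraries, with log2 fold changes of -0.11 ± 0.12 and -0.05 ± 0.13 (adjusted p = 0.61 and 0.87). Cdh5 (ENSMUSG00000031871; chromosome 8, 104101625 to 104144511, plus strand), the endothelial cadherin whose promoter drives the recombinase, averaged 886 ± 28.4 (SD), 1024 ± 86.5 and 912 ± 70.6 CPM in oil, CCl4 fl/fl and Brd4 LSECKO, with log2 fold changes of 0.21 ± 0.12 and -0.17 ± 0.12 (adjusted p = 0.28 and 0.46). None of the 3 passed the threshold in either comparison.

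The first comparison asks what CCl4 does to the liver's non-parenchymal cells. Monocyte/macrophage cells made up 14.9% ± 3.33 (SD) of the cells in CCl4 fl/fl against 1.18% ± 0.360 in oil, while endothelial cells made up 15.8% ± 5.25 against 52.2% ± 1.23. Kupffer cells, the resident macrophages of the sinusoids, made up 1.08% ± 1.17 against 5.59% ± 2.99. In endothelial cells the monocyte chemoattractant Ccl2 was higher. Of 16 sinusoidal identity genes 11 were lower and 1 was higher, and 10 of 16 capillary and 9 of 16 matrix genes were higher (adjusted p = 0.20, 0.23 and 0.088 for the lists with an estimated correlation). In Kupffer cells all 14 measured cell cycle genes were higher (adjusted p = 0.060 for the list with an estimated correlation).

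In these 3 classes the 3 CCl4 fl/fl libraries lay apart from the 3 oil libraries, which gives p = 0.1, the smallest an exact permutation test of 3 against 3 allows, and an adjusted p of 0.156. Neutrophils were at 6.42% ± 2.64 against 0.654% ± 0.170 and conventional dendritic cells at 4.60% ± 0.378 against 1.39% ± 0.198, with the same p. Stellate cells, the main collagen producers of the injured liver, were at 1.72% ± 1.25 against 0.740% ± 0.550 (exact permutation p = 0.4), a difference within the spread between libraries. NK and innate lymphoid cells, cholangiocytes, plasmacytoid dendritic, plasma and mesothelial cells also lay apart from oil, while T cells (9.07% ± 2.85 against 12.9% ± 1.72, exact permutation p = 0.2), B cells (p = 1) and hepatocytes (p = 0.6) did not. Single libraries moved some of these values. The Kupffer mean in CCl4 fl/fl was 0.407% ± 0.0987 without CCl4 fl/fl 3, and the Kupffer difference of -4.51 percentage points was -2.86 without oil 1. The stellate difference of 0.98 points was 0.44 without CCl4 fl/fl 2. Without CCl4 fl/fl 3 it was 1.66 and the groups lay apart (exact permutation p = 0.1). The T cell difference of -3.83 points was -2.32 without CCl4 fl/fl 2, and the groups lay apart without CCl4 fl/fl 3 (exact permutation p = 0.1) or oil 1 (p = 0.2). Hepatocytes lay apart without CCl4 fl/fl 2 (exact permutation p = 0.1). Genes that differed between the groups, such as Clec4f and C6 in Kupffer cells and Fn1 and Ccl9 in monocyte/macrophage cells, are among those that define these clusters. After clustering without defining genes, monocyte/macrophage cells were at 17.2% ± 2.61 against 1.35% ± 0.362 and endothelial cells at 13.4% ± 4.70 against 42.3% ± 1.89 (exact permutation p = 0.1 each), while Kupffer cells were at 3.87% ± 1.92 against 6.37% ± 3.07 (p = 0.3) and no longer lay apart, nor did they at Leiden resolution 0.5 (5.16% ± 2.15 against 6.99% ± 3.23, p = 0.5). Without defining genes T cells went the other way, at 10.7% ± 2.20 against 4.93% ± 0.820 (exact permutation p = 0.1). The T class leaves out the unnamed cluster 21, led by Cd8a and Ccl5, which held 6.44% ± 1.57 of all cells against 1.5% ± 0.468 in oil. The direction of the T cell difference thus depends on where that cluster is counted.

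**Figure D1:**
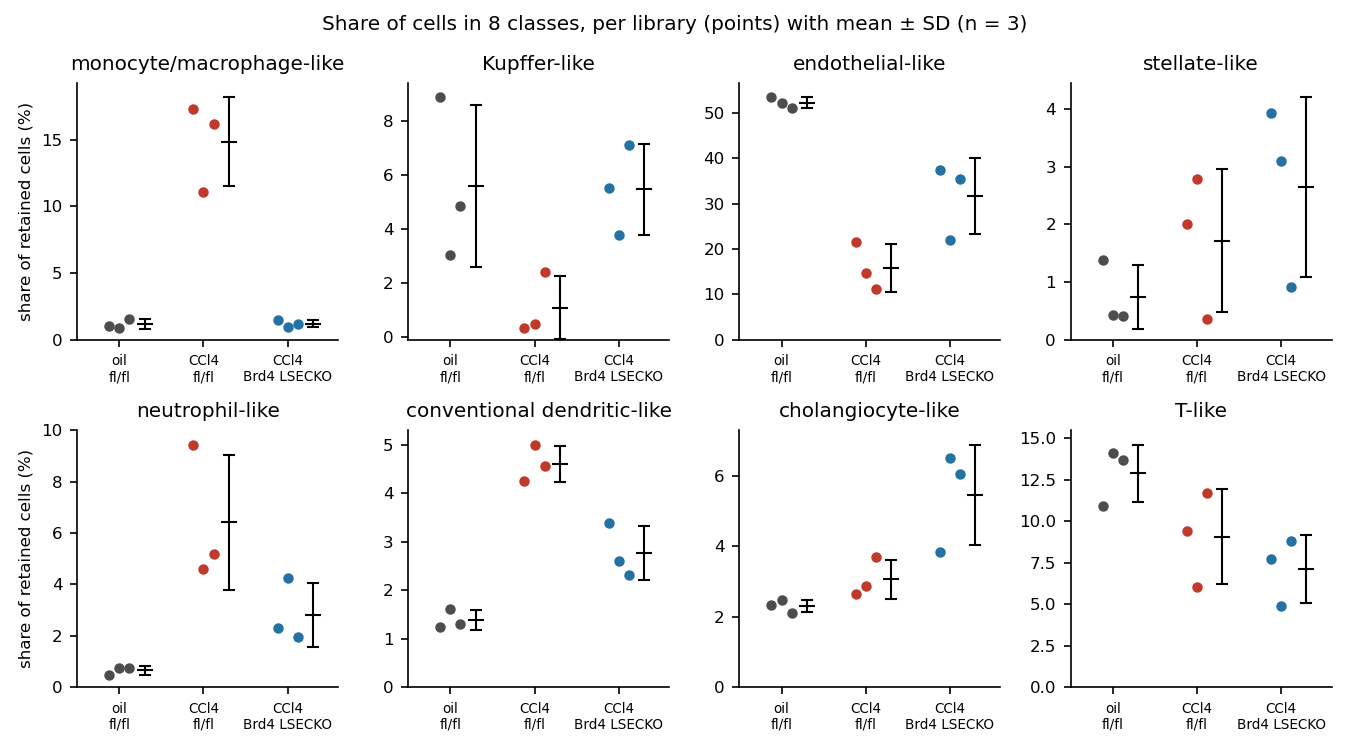
Share of retained cells (%, vertical axis) that fell into each of 8 cell classes, per library (points) with the mean and SD of the 3 libraries of each group. Monocyte/macrophage cells lie at 14.9% on average in CCl4 fl/fl against 1.18% in oil and 1.21% in Brd4 LSECKO, and endothelial cells at 15.8% against 52.2% and 31.6%.

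In endothelial cells 1896 of 13443 genes differed between CCl4 fl/fl and oil, 1134 higher and 762 lower. Ccl2 (ENSMUSG00000035385; chromosome 11, 82035571 to 82037453, plus strand, in GRCm38), the ligand that draws Ccr2-positive monocytes, rose from 3.45 ± 1.08 CPM (SD) to 47.2 ± 21.3 CPM (log2 fold change 3.80 ± 0.51 (SE), adjusted p = 0.00063). Whether RNA of monocyte/macrophage cells, whose share of cells rose as well, adds to Ccl2 in this class was not tested. Of 16 sinusoidal identity genes 11 fell, 1 rose and 4 did not pass (12 fell and 1 rose when adjusted over the list alone), among them the DNase Dnase1l3 (-1.41 ± 0.13) and the endocytic trafficking gene Ehd3 (-1.82 ± 0.17). The list as a whole lay lower (camera adjusted p = 2.1e-09, and adjusted p = 0.20 with an estimated correlation). Dnase1l3 is also one of the markers that named sinusoidal clusters, which the class pools with vascular ones. Of 16 capillarization and basement membrane genes 10 rose and none fell (11 and 1 when adjusted over the list alone; adjusted p = 7.5e-07, and 0.23 as adjusted p with an estimated correlation), led by the tip cell gene Esm1 (2.90 ± 0.29), Cd34 (2.12 ± 0.25) and the platelet-binding factor Vwf (2.42 ± 0.29). Over the 3 libraries of a group, cluster 4 held the largest part of the endothelial class in CCl4 fl/fl, and clusters 2 and 7 most of it in oil. Cluster 5, with Edn1, Selp and Vwf among its leading genes, and cluster 6, led by Esm1, held 5.25% ± 1.23 (SD) and 16.7% ± 16.1 of the class in CCl4 fl/fl against 1.85% ± 0.239 and 3.62% ± 2.54 in oil.

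Adhesion and inflammatory genes moved in the endothelial class too. Of 16 chemokine and leukocyte adhesion genes 6 rose and 2 fell (6 and 3 when adjusted over the list alone), with the selectins Selp (2.67 ± 0.24) and Sele (2.50 ± 0.36) higher and the macrophage growth factor Csf1 lower (-0.95 ± 0.19). That list's camera call (adjusted p = 0.022) gave an adjusted p of 0.37 with an estimated correlation and was lost without oil 3 (adjusted p = 0.087). Of 15 NF-kB feedback and target genes 3 rose (7 when adjusted over the list alone; adjusted p = 0.00027, and adjusted p = 0.26 with an estimated correlation), among them the NF-kB inhibitor Tnfaip3 (1.67 ± 0.18). The list of 12 BET and P-TEFb genes held a single call, the growth regulator Myc (2.93 ± 0.24). Myc itself encodes neither a BET protein nor a part of P-TEFb. Of the 14 PML nuclear body genes 2 rose and 2 fell, among the latter the nuclear body protein Sp100 (-0.58 ± 0.11). Of 18 angiocrine and vasoactive genes 9 rose and 4 fell (9 and 6 when adjusted over the list alone; adjusted p = 0.10 for the list, and 0.028 without CCl4 fl/fl 1), including the vasoconstrictor Edn1 (1.63 ± 0.26) and the hepatocyte growth factor Hgf (1.38 ± 0.23). Of 16 fibrillar collagen and matrix genes 9 rose (11 when adjusted over the list alone; adjusted p = 7.5e-07, and adjusted p = 0.088 with an estimated correlation), such as the crosslinking enzyme Lox (2.95 ± 0.35), Col5a2 (1.51 ± 0.19) and Fbn1 (0.95 ± 0.14). The largest changes included the neuropeptide Nts (6.45 ± 0.55), the scavenging chemokine receptor Ackr3 (3.18 ± 0.22) and Gpr155 (-2.39 ± 0.15).

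Transcripts of other cell types moved beside these groups in the endothelial class. Of 22 hepatocyte transcripts 10 rose (14 when adjusted over the list alone; adjusted p = 7.7e-07, and adjusted p = 0.37 with an estimated correlation), such as Apob (1.99 ± 0.33). Of 16 Kupffer identity genes 7 fell (11 when adjusted over the list alone; adjusted p = 0.00037, and adjusted p = 0.37 with an estimated correlation). Of 18 immediate early and heat shock genes, which can follow handling, 2 rose and 2 fell. That list lay lower with an adjusted p of 0.083 (adjusted p = 0.80 with an estimated correlation). Its adjusted p was 0.020 with the replicate block, which pairs the libraries by number, 0.0010 without oil 3, 0.013 without CCl4 fl/fl 1 and 0.030 without CCl4 fl/fl 2. The count of 1896 genes fell to 1078 without oil 1, 1146 without oil 3 and 1159 without CCl4 fl/fl 1.

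**Figure D2:**
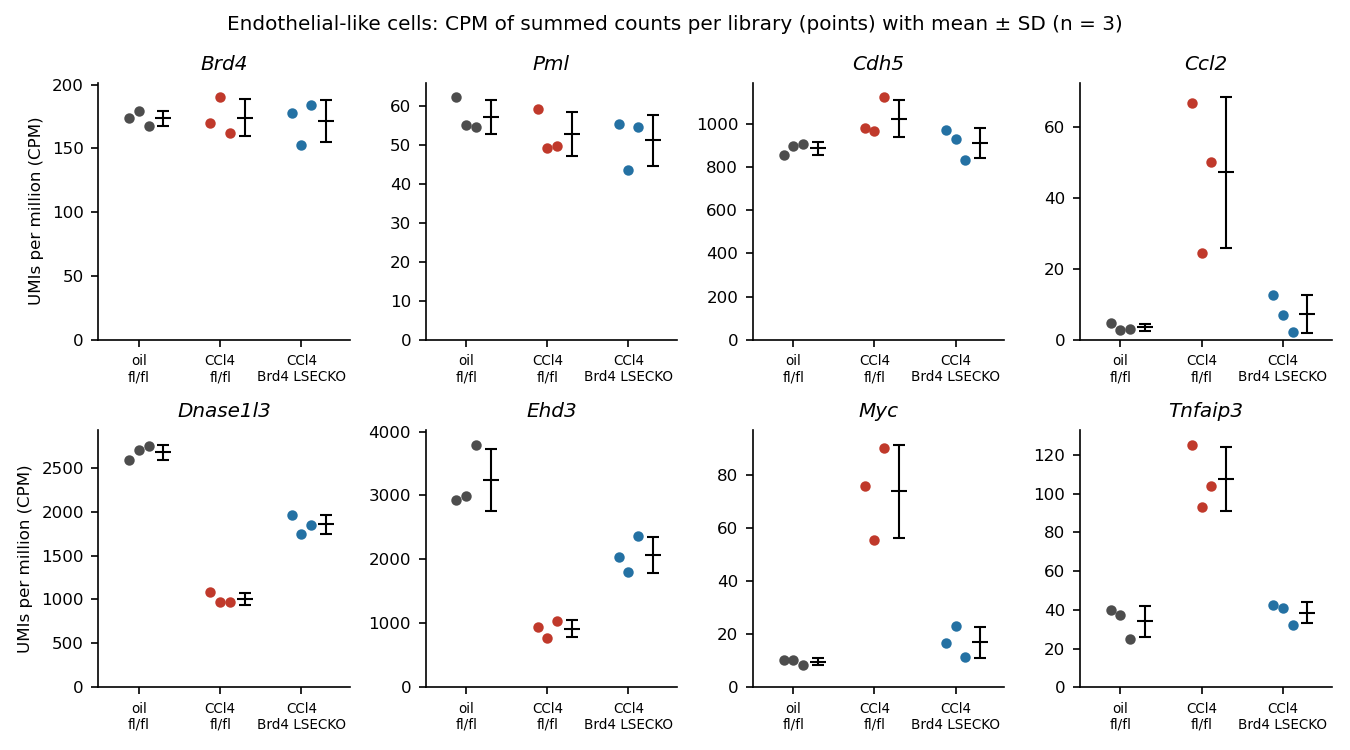
Expression in endothelial cells (vertical axis, CPM of counts summed per library) of Brd4, Pml, Cdh5, Ccl2, Dnase1l3, Ehd3, Myc and Tnfaip3, per library (points) with the mean and SD of the 3 libraries of each group. Brd4 lies between 152.55 and 190.24 CPM in all 9 libraries, while Ccl2 averages 47.2 CPM in CCl4 fl/fl against 3.45 CPM in oil and 7.29 CPM in Brd4 LSECKO.

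In Kupffer cells 2425 of 10281 genes differed, 1323 higher and 1102 lower in CCl4 fl/fl. All 14 cell cycle genes rose (adjusted p = 3.2e-11, and adjusted p = 0.060 with an estimated correlation), with the topoisomerase Top2a at 107 ± 23.0 CPM against 7.67 ± 4.44 CPM (log2 fold change 3.66 ± 0.35) and the replication licensing factor Mcm5 at 3.79 ± 0.46. Of 17 lipid- and scar-associated macrophage genes 11 rose (13 rose and 1 fell when adjusted over the list alone; adjusted p = 8.4e-07, and adjusted p = 0.060 with an estimated correlation), led by the elastase Mmp12 (4.61 ± 0.38) and the tetraspanin Cd63 (3.56 ± 0.36). Of 12 inflammatory monocyte genes 7 rose (8 when adjusted over the list alone; adjusted p = 0.00045, and adjusted p = 0.060 with an estimated correlation), among them S100a4 (2.68 ± 0.37). Of 16 Kupffer identity genes 8 fell and 1 rose, a list that shares genes with the markers by which the class was recognised and is no independent result. The efferocytosis and C1q list held 5 falls among 13 genes (adjusted p = 0.0027, and adjusted p = 0.15 with an estimated correlation), including the phagocytic receptor Mertk (-0.87 ± 0.20). Transcripts that can follow handling or free RNA also moved. In all, 11 of 18 immediate early and heat shock genes fell and 1 rose (adjusted p = 1.6e-05, and adjusted p = 0.23 with an estimated correlation). Of 16 sinusoidal endothelial genes 10 fell (adjusted p = 8.4e-07, and adjusted p = 0.21 with an estimated correlation). The CCl4 fl/fl libraries held only 30, 74 and 198 Kupffer cells, and without CCl4 fl/fl 3 the count of genes was 1543. The class leaves out the unnamed cluster 14, led by Mmp12 and Mmp13, which held 3.64% of all cells in CCl4 fl/fl against 0.812% in oil.

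In monocyte/macrophage cells 222 of 6991 genes differed, 86 higher and 136 lower. Of 19 interferon-stimulated genes 8 rose and none fell (14 when adjusted over the list alone; adjusted p = 3.6e-09, and adjusted p = 0.50 with an estimated correlation), with the ubiquitin-like modifier Isg15 at 121 ± 31.1 CPM against 31.0 ± 16.7 CPM (1.90 ± 0.33) and Rtp4 at 2.57 ± 0.30. The leukotriene C4 synthase gene Ltc4s (-4.42 ± 0.53) and the arginine transporter gene Slc7a2 (-2.89 ± 0.37) fell. Of 18 immediate early and heat shock genes 2 fell in this class (7 when adjusted over the list alone; adjusted p = 0.0011, and adjusted p = 0.77 with an estimated correlation). It held 90, 109 and 121 cells in the oil libraries, and the count of genes was 93 without oil 1, 89 without oil 2 and 53 without oil 3.

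In stellate cells 474 of 9701 genes differed, 159 higher and 315 lower. Of 21 collagen and matrix genes 8 rose and none fell (9 and 1 when adjusted over the list alone; adjusted p = 5.7e-05, and adjusted p = 0.52 with an estimated correlation), with Col1a1, the main fibrillar collagen gene, at 6466 ± 3594 CPM against 1219 ± 107 CPM (2.40 ± 0.34, adjusted p = 0.0054). Of 14 quiescence genes 6 fell (9 fell and 1 rose when adjusted over the list alone; adjusted p = 9.2e-05, and adjusted p = 0.52 with an estimated correlation), among them the VIP receptor Vipr1 (-3.56 ± 0.40). The TGF-beta and PDGF list held 1 rise, the matrix protein gene Ltbp2 (3.25 ± 0.47), among 13 genes (adjusted p = 0.00053, and adjusted p = 0.33 with an estimated correlation), and 1 of 10 contractile genes rose (adjusted p = 0.83). Sinusoidal endothelial transcripts fell in this class (5 of 16, and 15 when adjusted over the list alone; adjusted p = 4.1e-12, and adjusted p = 0.33 with an estimated correlation). Of 18 immediate early and heat shock genes 3 fell (adjusted p = 0.00053, and adjusted p = 0.49 with an estimated correlation). The smallest library held 29 stellate cells, and the count was 81 without oil 1, 139 without oil 2, 127 without oil 3, 92 without CCl4 fl/fl 1, 957 without CCl4 fl/fl 2 and 212 without CCl4 fl/fl 3.

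The other 8 tested classes gave 3768 calls together, of which T cells gave 1416 (811 higher and 605 lower), conventional dendritic cells 872, cholangiocytes 708, hepatocytes 412, NK and innate lymphoid cells 245 and B cells 115. Hepatocytes lay mostly in cluster 12 in oil and in cluster 33 in CCl4 fl/fl, and T cells mostly in cluster 22 in oil and in cluster 24 in CCl4 fl/fl. The conventional dendritic class pools clusters 17 and 36. Cluster 36 held 1.41% ± 0.73 (SD) of all cells in CCl4 fl/fl and 0.094% ± 0.035 in oil. Cluster 17 held 3.19% ± 0.78 and 1.29% ± 0.16. Neutrophils gave 0 calls by edgeR (782 genes at an unadjusted p under 0.05, and 99 calls by DESeq2), and plasmacytoid dendritic cells 0 (429, and 3 by DESeq2). The sum was 1952 without CCl4 fl/fl 1, 1855 without oil 1, 2097 without oil 2 and 2098 without oil 3.

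**Figure D3:**
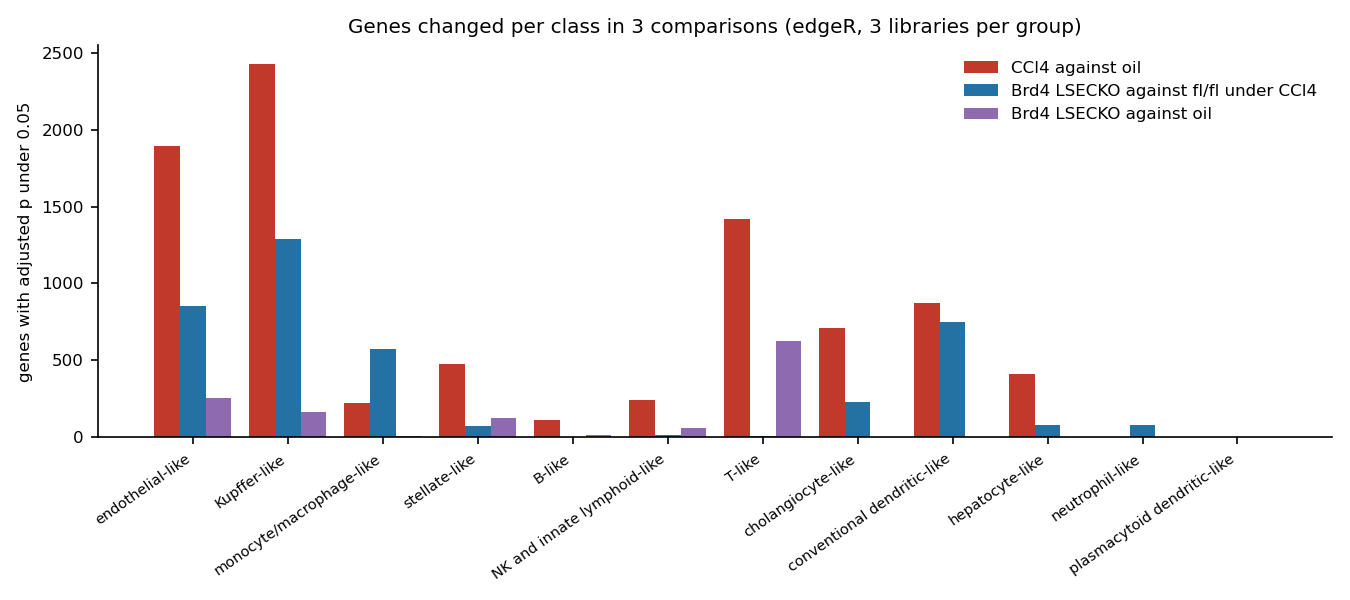
Number of genes past an adjusted p of 0.05 by edgeR (vertical axis) in each of the 12 tested classes, for CCl4 against oil, Brd4 LSECKO against CCl4 fl/fl, and Brd4 LSECKO against oil. Kupffer cells lead the first 2 with 2425 and 1287 genes, and T cells lead the last with 629.

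The second comparison sets Brd4 LSECKO against CCl4 fl/fl. The labels give tamoxifen and the recombinase for the Brd4 LSECKO mice and do not say whether the fl/fl mice had either, so the groups may differ in these as well as in Brd4. Monocyte/macrophage cells made up 1.21% ± 0.274 of the cells in Brd4 LSECKO against 14.9% ± 3.33 in CCl4 fl/fl, endothelial cells 31.6% ± 8.40 against 15.8% ± 5.25, and Kupffer cells 5.47% ± 1.68 against 1.08% ± 1.17. In endothelial cells Ccl2 fell to 7.29 ± 5.29 CPM, with Myc and Tnfaip3 also lower, and 5 of 16 sinusoidal identity genes were higher (adjusted p = 0.46 for the list with an estimated correlation). In Kupffer cells all 14 cell cycle and 9 of 17 scar-associated genes were lower and 6 of 16 antigen presentation genes were higher (adjusted p = 0.084, 0.084 and 0.19 for the lists with an estimated correlation).

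For these 3 classes the 3 libraries of each group again did not overlap (exact permutation p = 0.1, the smallest allowed, adjusted p = 0.156). Neutrophils (2.82% ± 1.24 against 6.42% ± 2.64) and conventional dendritic cells (2.77% ± 0.557 against 4.60% ± 0.378) lay apart with the same p. Stellate cells were at 2.65% ± 1.56 against 1.72% ± 1.25 (exact permutation p = 0.4, which ignores replicate numbers). By replicate number their share was 3.94% against 2.01%, 3.10% against 2.80% and 0.920% against 0.355%, higher in Brd4 LSECKO each time. T cells were at 7.12% ± 2.03 against 9.07% ± 2.85 (exact permutation p = 0.4). Cluster 21, led by Cd8a and Ccl5 and left out of that class, held 5.5% ± 2.23 against 6.44% ± 1.57. The stellate difference of 0.93 points was 0.25 without CCl4 fl/fl 3, 0.29 without Brd4 LSECKO 1 and 1.47 without CCl4 fl/fl 2. Without Brd4 LSECKO 3 it was 1.80 and the groups lay apart (exact permutation p = 0.2). The T cell difference of -1.95 points was -0.62 without CCl4 fl/fl 3, -0.82 without Brd4 LSECKO 2 and, then apart, -3.46 without CCl4 fl/fl 2. The neutrophil difference of -3.60 points was -2.08 without CCl4 fl/fl 1. Monocyte/macrophage cells were 21.4%, 20.4% and 14.1% of all Kupffer and monocyte/macrophage cells in the Brd4 LSECKO libraries, against 98.1%, 95.9% and 87.0% in CCl4 fl/fl. These parts leave out the unnamed cluster 14, which held 3.52% ± 0.272 of all cells in Brd4 LSECKO and 3.64% ± 0.194 in CCl4 fl/fl. Its leading genes held 4 monocyte/macrophage and 3 Kupffer markers, and another class led among the top 10. In the CCl4 fl/fl libraries the Kupffer class went from 30, 74 and 198 cells to 338, 628 and 624 at Leiden resolution 0.5. The monocyte/macrophage class went from 1542, 1718 and 1323 to 1639, 4005 and 1427. Cluster 14 may thus belong with Kupffer cells, but where its cells went was not traced. Counted with monocyte/macrophage cells, cluster 14 gives 47.2%, 53.1% and 41.2% against 98.4%, 96.8% and 89.2%. Counted with Kupffer cells, it gives 14.4%, 11.99% and 9.67% against 81.4%, 73.8% and 72.1%. Both were chosen after the data were seen. Clustered without defining genes, monocyte/macrophage cells were at 1.77% ± 0.230, endothelial cells at 27.0% ± 6.24 and Kupffer cells at 8.88% ± 1.92, each still apart from CCl4 fl/fl (exact permutation p = 0.1).

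In endothelial cells 856 genes differed, 305 higher and 551 lower in Brd4 LSECKO. The log2 fold change of Ccl2 was -2.69 ± 0.48 (adjusted p = 0.011), with 12.771, 6.8829 and 2.2047 CPM in the 3 libraries; without CCl4 fl/fl 1 its adjusted p was 0.057. Ccl2 was the 1 chemokine or adhesion gene of 16 to pass (adjusted p = 0.26 for the list). The share of monocyte/macrophage cells fell too, and whether their RNA adds to Ccl2 in this class was not tested. Of 16 sinusoidal identity genes 5 rose and none fell (6 when adjusted over the list alone; adjusted p = 5.5e-06, and adjusted p = 0.46 with an estimated correlation), with Dnase1l3 at 0.88 ± 0.12 and Ehd3 at 1.17 ± 0.17. Of 16 capillarization and basement membrane genes 4 fell (5 when adjusted over the list alone; adjusted p = 0.017, and adjusted p = 0.71 with an estimated correlation), such as the basement membrane collagen Col4a2 (-0.94 ± 0.15). That list call was lost without CCl4 fl/fl 3 (adjusted p = 0.14) and without Brd4 LSECKO 3 (0.059). Of 15 NF-kB genes 3 fell (7 when adjusted over the list alone; adjusted p = 6.9e-05, and adjusted p = 0.46 with an estimated correlation), with Tnfaip3 at -1.48 ± 0.18. Of the 12 genes on the BET and P-TEFb list 3 fell, among them Myc (-2.13 ± 0.24), which belongs to neither group. The camera adjusted p of that list was 0.10, and 0.036 without CCl4 fl/fl 1 and 0.047 without Brd4 LSECKO 3. Of 14 PML nuclear body genes 2 rose and none fell.

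Further genes of this comparison included the endothelial nitric oxide synthase Nos3 (-0.90 ± 0.11), the anticoagulant receptor Thbd (-1.47 ± 0.17), Nts (-3.54 ± 0.46) and the urokinase receptor Plaur (-2.12 ± 0.27) among those that fell, and Gpr155 (1.46 ± 0.15) and the matrix proteoglycan Prelp (1.81 ± 0.23) among those that rose. Of 16 collagen and matrix genes 3 fell (adjusted p = 0.10 for the list). Kupffer identity genes rose in the endothelial class (3 of 16, and 8 when adjusted over the list alone; adjusted p = 0.017, and adjusted p = 0.80 with an estimated correlation). That call was lost without CCl4 fl/fl 3 (adjusted p = 0.13) and without Brd4 LSECKO 2 (0.083). The hepatocyte list lay lower with an adjusted p of 0.15 (adjusted p = 0.83 with an estimated correlation). Its adjusted p was 0.031 with the replicate block, 5.4e-06 without Brd4 LSECKO 2, 0.037 without CCl4 fl/fl 1 and 0.00017 without the 2 libraries richest in barcodes (CCl4 fl/fl 2 and Brd4 LSECKO 2). Cluster 4 held the largest part of the CCl4 fl/fl cells of this class, and clusters 2 and 7 most of the Brd4 LSECKO cells. The count of 856 genes was 225 without Brd4 LSECKO 1, 503 without Brd4 LSECKO 3, 268 without CCl4 fl/fl 1 and 539 without CCl4 fl/fl 3.

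In Kupffer cells 1287 genes differed, 474 higher and 813 lower. All 14 cell cycle genes fell (adjusted p = 3.3e-15, and adjusted p = 0.084 with an estimated correlation), Top2a by a log2 fold change of -2.68 ± 0.29. Of 17 scar-associated genes 9 fell (13 when adjusted over the list alone; adjusted p = 4.6e-08, and adjusted p = 0.084 with an estimated correlation), with Mmp12 at -4.28 ± 0.35 and the fatty acid transporter Cd36 at -1.46 ± 0.19. Of 16 antigen presentation genes 6 rose and none fell (8 and 1 when adjusted over the list alone; adjusted p = 5.3e-06, and adjusted p = 0.19 with an estimated correlation), led by the MHC class II genes H2-Aa (1.95 ± 0.26) and H2-Eb1 (1.88 ± 0.26) and the invariant chain Cd74 (1.60 ± 0.22). Of 21 interferon-stimulated genes 4 rose (5 when adjusted over the list alone; adjusted p = 0.0016, and adjusted p = 0.36 with an estimated correlation), including Irf1 (0.94 ± 0.18). Among cytokines Il1b rose (1.78 ± 0.34) and the monocyte attractant Ccl7 fell (-1.92 ± 0.46). Immediate early and heat shock genes moved as well (6 rose and 2 fell of 18; adjusted p = 0.00057, and adjusted p = 0.33 with an estimated correlation). Of 16 sinusoidal endothelial genes 5 rose (adjusted p = 6.6e-07, and adjusted p = 0.19 with an estimated correlation). The count was 699 without Brd4 LSECKO 1, 780 without Brd4 LSECKO 3 and 766 without CCl4 fl/fl 3. The Kupffer class leaves out the unnamed cluster 14, led by Mmp12 and Mmp13. That cluster held 3.52% ± 0.272 (SD) of all cells in Brd4 LSECKO and 3.64% ± 0.194 in CCl4 fl/fl.

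In monocyte/macrophage cells 571 genes differed, 317 higher and 254 lower. The lymph node homing receptor Sell (2.62 ± 0.29) and the transcription factor Bcl11a (2.52 ± 0.31) rose, while the membrane protease Mmp14 (-2.05 ± 0.35), the macrophage transcription factor Maf (-1.76 ± 0.23) and the liver X receptor Nr1h3 (-2.02 ± 0.35) fell. Of 17 scar-associated genes 5 fell (9 when adjusted over the list alone; adjusted p = 1.0e-06, and adjusted p = 0.74 with an estimated correlation). Of 15 inflammatory monocyte genes 2 rose (adjusted p = 0.00064, and adjusted p = 0.74 with an estimated correlation), and with the 2 libraries richest in barcodes left out that list had an adjusted p of 0.053. Of 13 macrophage cytokines 3 fell (5 when adjusted over the list alone; adjusted p = 0.0076, and adjusted p = 0.74 with an estimated correlation), a call lost without Brd4 LSECKO 3 (adjusted p = 0.058). The Brd4 LSECKO libraries held 126, 181 and 84 such cells, and the count was 380 without Brd4 LSECKO 2 and 203 without Brd4 LSECKO 3.

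In stellate cells 77 genes differed, 34 higher and 43 lower, and with the replicate block 384. The contractile gene Tagln was lower (-3.11 ± 0.40, adjusted p = 0.023), and Col1a1 was the 1 collagen and matrix gene of 21 to pass (-1.71 ± 0.33, adjusted p = 0.044; 8 fell when adjusted over the list alone). The list call of the matrix genes (adjusted p = 0.0013, and adjusted p = 0.58 with an estimated correlation) was lost without Brd4 LSECKO 2 (adjusted p = 0.15). Of 10 contractile genes Tagln alone fell (7 when adjusted over the list alone; adjusted p = 0.0013, and adjusted p = 0.58 with an estimated correlation), and that list call was lost without Brd4 LSECKO 2 as well (adjusted p = 0.058). The TGF-beta and PDGF list lay lower with an adjusted p of 0.063 (adjusted p = 0.58 with an estimated correlation), and of 0.039 with the replicate block, 0.031 without CCl4 fl/fl 2 and 0.020 without Brd4 LSECKO 3. Tagln no longer passed without CCl4 fl/fl 1 (adjusted p = 0.075), Brd4 LSECKO 1 (0.10) or Brd4 LSECKO 3 (0.11), nor Col1a1 without CCl4 fl/fl 1 (0.075), CCl4 fl/fl 3 (0.067), Brd4 LSECKO 1 (0.22), Brd4 LSECKO 2 (0.052) or Brd4 LSECKO 3 (0.17). The count of genes was 0 without Brd4 LSECKO 1, 0 without Brd4 LSECKO 3, 0 without CCl4 fl/fl 1, 10 without CCl4 fl/fl 3, 154 without Brd4 LSECKO 2 and 407 without CCl4 fl/fl 2.

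The other 8 classes gave 1160 calls together, of which conventional dendritic cells gave 747 (379 higher and 368 lower), cholangiocytes 230, hepatocytes 82, neutrophils 79, NK and innate lymphoid cells 16 and T cells 6. A split of the same 6 libraries that mixes the groups gave more for hepatocytes (110), NK and innate lymphoid cells (59) and T cells (17). B cells gave 0 calls by edgeR (776 genes at an unadjusted p under 0.05, and 27 calls by DESeq2), and plasmacytoid dendritic cells 0 (275, and 1 by DESeq2). Hepatocytes lay mostly in cluster 33 in CCl4 fl/fl and in cluster 12 in Brd4 LSECKO, and neutrophils mostly in cluster 32 in CCl4 fl/fl and in clusters 32 and 37 in Brd4 LSECKO. In the conventional dendritic class, cluster 36 held 0.18% ± 0.072 (SD) of all cells in Brd4 LSECKO and 1.41% ± 0.73 in CCl4 fl/fl. Cluster 17 held 2.59% ± 0.48 and 3.19% ± 0.78. The sum was 517 without Brd4 LSECKO 1, 421 without Brd4 LSECKO 3, 482 without CCl4 fl/fl 1, 1969 without CCl4 fl/fl 2 and 1844 without CCl4 fl/fl 3.

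**Figure D4:**
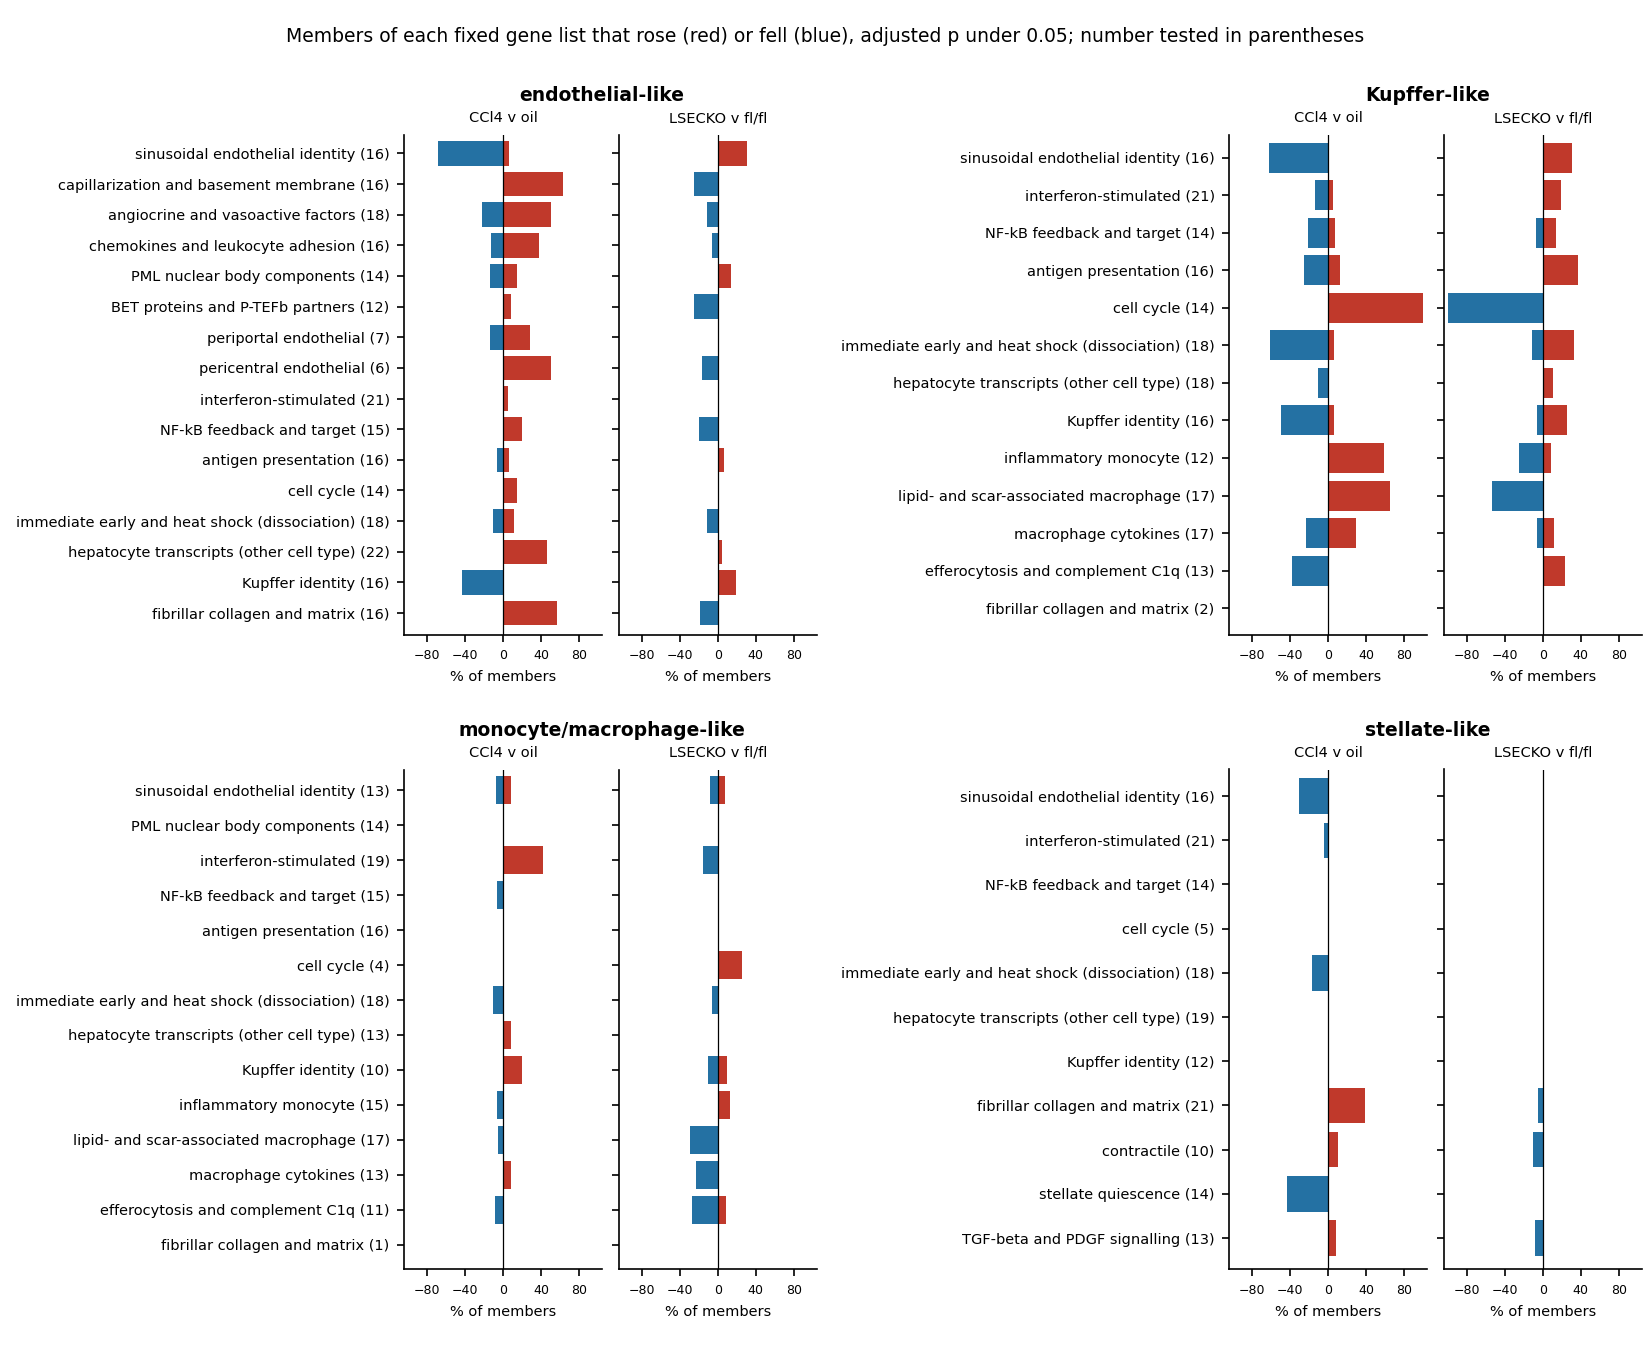
Percent of the tested members of each gene list that rose (red, to the right) or fell (blue, to the left) at an adjusted p under 0.05, in the 4 main classes and both comparisons, with the number of members tested in parentheses. In endothelial cells 11 of 16 sinusoidal identity genes fell under CCl4 and 5 rose in Brd4 LSECKO, and in Kupffer cells all 14 cell cycle genes rose and then fell.

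Genes that passed in both comparisons almost always did so in opposite directions. In endothelial cells 438 genes were higher under CCl4 and lower in Brd4 LSECKO and 222 the reverse, with 1 of the same sign, while independent lists would give 46.5 and 17.3. In Kupffer cells the numbers were 733, 413 and 1 (105 and 50.8 for independent lists). Both comparisons share the CCl4 fl/fl libraries, which alone gives a negative relation: the covariance of the log2 fold changes across genes, which are not independent replicates, was -0.251 in endothelial cells against -0.0558 ± 0.0013 in simulations of unchanged groups, and -0.600 in Kupffer cells against -0.103 ± 0.0037. It was -0.184 against -0.0314 in monocyte/macrophage cells (129 genes of opposite sign) and -0.345 against -0.0945 in stellate cells (44 genes). Splitting the shared libraries would leave a part with fewer than 2, so part of the excess over independent lists may come from them. The endothelial number of 660 opposite genes was 246 without CCl4 fl/fl 1, 357 and 439 without oil 1 and 3, and 213 and 403 without Brd4 LSECKO 1 and 3. The Kupffer number of 1146 was 682 without CCl4 fl/fl 3, and 664 and 705 without Brd4 LSECKO 1 and 3. The monocyte/macrophage number of 129 was 81 without CCl4 fl/fl 2, 61, 59 and 29 without oil 1, 2 and 3, and 78 without Brd4 LSECKO 3. The stellate number of 44 was 0, 262 and 8 without CCl4 fl/fl 1, 2 and 3, 3, 5 and 0 without oil 1, 2 and 3, and 0, 71 and 0 without Brd4 LSECKO 1, 2 and 3.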

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

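The tests in this part were chosen after the results were seen, except the splits of the libraries for the other named classes. Some unnamed clusters, which enter no comparison above, took a larger share of cells in CCl4 libraries than in any oil library; with 3 libraries against 3, chance separates the groups in one direction or the other in 10% of cases. Cluster 14, led by the metalloproteases Mmp12 and Mmp13, held 3.64% ± 0.194 (SD) of the cells in CCl4 fl/fl and 3.52% ± 0.272 in Brd4 LSECKO, against 0.812% ± 0.125 in oil. Cluster 21, led by the cytotoxic T cell genes Cd8a and Ccl5, held 6.44% ± 1.57 and 5.5% ± 2.23 against 1.5% ± 0.468. Cluster 26, of cycling cells led by Top2a, held 1.29% ± 0.719 and 1.42% ± 0.771 against 0.499% ± 0.203. Cluster 11, led by Ccl9, Chil3 and Fn1 and rich in called doublets, held 5.14% ± 7.59 in CCl4 fl/fl against 0.422% ± 0.0346, with 13.9% in the highest library. The doublet-rich clusters 30 (Ebf1, Pax5) and 35 (C1qc, Folr2) held 0.439% ± 0.496 and 0.355% ± 0.29 in CCl4 fl/fl against 0.0854% and 0.0568% in oil, and cluster 35 held 0.431% ± 0.258 in Brd4 LSECKO.

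Of 16 collagen and matrix genes 9 rose in endothelial cells under CCl4 (adjusted p = 0.088 for the list with an estimated correlation), and stellate cells are a candidate source of such RNA. For the members at 10 CPM or more in oil (such as Col5a2, Fbn1 and Eln), the tables argue against it: their summed CPM rose in B and T cells, which should lack them, by 0.8192% of the rise in endothelial cells, and the 10 most abundant stellate-specific genes allow 0.01445 times the share of stellate RNA these members need. For the members under 10 CPM in oil (Col1a1, Col6a3, Lox, Mmp2 and Timp1) the same values were 24.99% and 0.3666, between the bounds set for either answer, so free RNA and doublets cannot be told apart from expression by endothelial cells for that part as a whole. Its members differ: in CCl4 fl/fl, Col1a1 stood at 7.72 ± 5.49 CPM (SD) in B and T cells and 7.57 ± 5.12 in endothelial cells, but Lox at 0.069 ± 0.12 and 9.29 ± 2.22 and Mmp2 at 0.36 ± 0.14 (0.35 in oil) and 1.65 ± 0.19, which goes against free RNA for these 2. A change in the endothelial cells themselves may account for the first part and stays open for the second, as a hypothesis from the same data.

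All 14 cell cycle genes and 7 of 12 inflammatory monocyte genes rose in Kupffer cells under CCl4 (adjusted p = 0.060 for either list with an estimated correlation), and monocyte/macrophage cells or their RNA in that class are a candidate explanation. For the cell cycle genes the tables argue against it, since their summed CPM in monocyte/macrophage cells was at most 32.26% of that in Kupffer cells in the 3 CCl4 fl/fl libraries. For the monocyte genes, 7 of the 7 that rose lay within 4 times the share of monocyte/macrophage RNA that the 50 most abundant specific genes give, so such RNA may account for that part. Division of resident cells under CCl4, the biological alternative, stays open for the first part, as does a shift of dividing cells into this class by the clustering. Doublets with dividing cells were not tested and stay open too. Median UMIs per Kupffer cell were 4904, 2655.5 and 8413 in CCl4 fl/fl against 2006, 1450 and 1951 in oil.

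The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 1896 genes in endothelial cells for CCl4 against oil, with 0 as the highest other, and 1 of the 10 splits gave as many; the numbers were 2425 and 0 in Kupffer cells, 222 and 1 in monocyte/macrophage cells, 474 and 0 in stellate cells, and 3768 and 0 in the other classes, again 1 of the 10 splits each. For Brd4 LSECKO against CCl4 fl/fl they were 856 and 64 in endothelial cells, 1287 and 9 in Kupffer cells, 571 and 0 in monocyte/macrophage cells and 1160 and 245 in the other classes, with 1 of the 10 splits as large. Within that sum another split gave more than the real one in hepatocytes (110 against 82), NK and innate lymphoid cells (59 against 16), T cells (17 against 6), B cells (35 against 0) and plasmacytoid dendritic cells (147 against 0). In stellate cells 2 of the 10 splits gave as many genes as the real 77; the other, of CCl4 fl/fl 1, Brd4 LSECKO 1 and Brd4 LSECKO 3 against the rest, gave 107. In the endothelial and stellate classes the numbers were taken to pair the libraries. There the real split parts all 3 pairs, and the 3 other splits that do so gave 0 genes each by edgeR. The split that gave 64 genes in endothelial cells keeps the pairs numbered 2 and 3 together, and the one that gave 107 those numbered 1 and 2; every split that does not part all 3 pairs keeps 2 of them.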

How the results depend on the processing

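At most 10% mitochondrial UMIs, at least 500 genes, doublets by expected rate, DESeq2 size factors in the edgeR fit and another denominator changed no count of genes by over 1.5 times and no share's direction or call. The 2 libraries left out, the expected rate, doublet-rich clusters over all libraries, genes under 10% of the highest class and the re-clustering were chosen after seeing the data. The cause was not tested for any of the changes given here. Without each library in turn, the lowest and highest counts were, for CCl4 against oil, 1078 and 1622 in endothelial, 1543 and 2419 in Kupffer, 53 and 267 in monocyte/macrophage, 81 and 957 in stellate cells and 1855 and 4846 in the other classes, and for Brd4 LSECKO 225 and 990, 699 and 1381, 203 and 590, 0 and 407, and 421 and 1969. The numbers of opposite genes ran from 213 to 801, 664 to 1211, 29 to 141 and 0 to 262. The 0 in stellate cells is by edgeR. Of 332 values of named genes 154 lost a call without at least 1 library and 3 changed sign; 68 lost it at Leiden resolution 0.5, 12 with DESeq2 and 2 with the replicate block.

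For CCl4 against oil, no filter on low counts gave 696 genes in monocyte/macrophage cells, 1264 in stellate cells and 7810 in the other classes. With the 2 libraries richest in barcodes (CCl4 fl/fl 2 and Brd4 LSECKO 2) left out these were 106, 1336 and 6445. DESeq2 gave 399 and Leiden resolution 0.5 gave 47 in monocyte/macrophage cells, and 33 came from doublet-rich clusters judged over all libraries. Kupffer cells gave 4345 at Leiden resolution 0.5 and 1092 when thinned, and stellate cells 778 with doublets kept.

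For Brd4 LSECKO against CCl4 fl/fl, the 6 libraries alone gave 410 genes in endothelial, 831 in Kupffer and 0 in stellate cells (1717 at an unadjusted p under 0.05 in the fit of 9) and 601 in the other classes. Kupffer cells gave 3008 at Leiden resolution 0.5 and 541 when thinned. Monocyte/macrophage cells gave 196 without the 2 libraries, 84 with doublet-rich clusters judged over all libraries, 107 at resolution 0.5 and 1043 with no filter. Stellate cells gave 565 without the 2 libraries, 194 with doublets kept, 371 with DESeq2, 208 without genes under 10% of the highest class and 575 with no filter. The other classes gave 2248 with doublets kept and 4039 with no filter.

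Opposite genes numbered 367 in endothelial cells in the 6 libraries alone. In Kupffer cells they numbered 2607 at resolution 0.5, 467 thinned and 729 in the 6 libraries. In monocyte/macrophage cells they numbered 208 with DESeq2, 335 with no filter, 21 at resolution 0.5, 82 thinned, 15 with doublet-rich clusters over all libraries, 45 without the 2 libraries and 74 in the 6. In stellate cells they numbered 163 with DESeq2, 317 with no filter, 100 with doublets kept, 96 without genes under 10%, 341 without the 2 libraries and 0 in the 6.

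With edgeR on cell counts, which unlike the permutation test can pass with 3 against 3, the log2 ratios for CCl4 and Brd4 LSECKO were 3.66 and -3.62 for monocyte/macrophage, -1.73 and 1.00 for endothelial and -2.38 and 2.35 for Kupffer cells, all past the threshold. The replicate block gave 3.66 and -3.60, -1.76 and 1.01, and -2.67 and 2.61. Of the lists, 27 and 23 passed at the preset correlation, 0 and 0 with an estimated one, and 28 and 26 with the block. Every library correlated best with one of its own number in endothelial and monocyte/macrophage cells (9 of 9), and 8 of 9 did in Kupffer and stellate cells. With the replicate block the counts were 2386 and 1089 in endothelial, 2535 and 1451 in Kupffer, 347 and 701 in monocyte/macrophage, 964 and 384 in stellate cells and 6039 and 2741 in the other classes, with 847, 1283, 183 and 183 opposite genes in the 4 classes. Apart from the immediate early list under CCl4 and the hepatocyte list in Brd4 LSECKO in endothelial cells and the TGF-beta list in stellate cells, given above, the block changed no call of a gene or list the report describes.

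Signs turned as follows. Brd4 in endothelial cells had log2 fold changes for CCl4 of -0.0024 with DESeq2, -0.053 with no filter, -0.0063 at resolution 0.5, -0.054 without the 2 libraries and -0.055 to 0.042 without single libraries, and for Brd4 LSECKO of 0.019 with no filter, 0.11 without the 2 libraries and -0.076 to 0.048 without single libraries. For Pml in Brd4 LSECKO, single libraries left out gave -0.10 to 0.043. With no filter, signed -log10 p values in monocyte/macrophage cells under CCl4 were 0.33 for NF-kB, 0.14 for immediate early and 1.77 for inflammatory monocyte genes, and -2.38 for immediate early genes in Brd4 LSECKO. With no filter, the capillarization list in Brd4 LSECKO (adjusted p = 0.37) and the chemokine list under CCl4 (0.056) lost their endothelial calls. The stellate cell cycle list in Brd4 LSECKO was at -2.62 without CCl4 fl/fl 1 and reached 0.90 without CCl4 fl/fl 2. Depth may limit the smaller classes, since 2-fold changes in stellate cells were seldom recovered in simulated data. Thinning lowered the Kupffer counts, but the number of genes tested fell too, from 10281 to 3787.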

Other observations

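The comparison and tests in this part were chosen after the data were seen, except the test of pericentral hepatocyte genes. Brd4 LSECKO libraries were also set against the oil libraries. T cells showed the most differences, 629 of 11182 genes, 368 higher and 261 lower in Brd4 LSECKO. Among the genes higher in Brd4 LSECKO were the regulatory T cell factor Foxp3 (log2 fold change 3.49 ± 0.45 (SE)), the checkpoint receptor Ctla4 (2.61 ± 0.31), the IL-33 receptor Il1rl1 (4.09 ± 0.47) and Il10 (4.55 ± 0.62). Among the lower ones were the factor Zbtb16 (-1.58 ± 0.16), Il4 (-1.53 ± 0.26) and the receptor Cd160 (-1.80 ± 0.14). These genes were chosen after their values were seen. Of the T clusters, 22 was the largest in oil and 24 in both CCl4 groups. Cluster 22 held 9.13% ± 1.37 (SD) of all cells in oil and 1.66% ± 0.491 in Brd4 LSECKO. At Leiden resolution 0.5 the T cluster led by Il4 and Zbtb16 held 675, 1274 and 739 cells in oil and 156, 257 and 170 in Brd4 LSECKO. An unnamed cluster at that resolution, with Foxp3, Ctla4, Il1rl1 and Il10 among its leading genes, held 4, 14 and 8 cells in oil. In Brd4 LSECKO it held 167, 88 and 110. More cells of that kind may thus lie behind the rise of these genes, though which class held them at resolution 1.0 was not traced. For the other genes, changes within cells and in the mix of clusters cannot be told apart here. The class leaves out the unnamed cluster 21, led by Cd8a and Ccl5. The neutrophil transcript S100a8 was higher in the class as well (3.03 ± 0.59). Of the T cell genes, 323 were higher and 227 lower against oil in both CCl4 groups and 0 went opposite ways by edgeR (26.7 and 14.1 for independent lists). Both effects use the same oil libraries, which alone favours changes of the same sign. The real split gave 629 genes and the highest other 0; 1 of the 10 splits gave as many, too few splits for a share under 0.05. The count was 363 without oil 3, 387 without oil 1, 402 without oil 2 and 388 without Brd4 LSECKO 1.

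Between Brd4 LSECKO and oil, endothelial cells differed in 259 genes, Kupffer cells in 162, stellate cells in 124 and monocyte/macrophage cells in 12. Conventional dendritic cells, with 747 calls against CCl4 fl/fl, gave 0 against oil by edgeR (521 genes at an unadjusted p under 0.05, and 0 by DESeq2), but 163 with no filter on low counts, 32 without the 2 libraries richest in barcodes and 7 at Leiden resolution 0.5. The endothelial count was 66 without oil 1, 93 without oil 2, 134 without oil 3, 95 without Brd4 LSECKO 1, 160 without Brd4 LSECKO 2 and 429 without Brd4 LSECKO 3. The Kupffer count was 38 without oil 1, 80 without oil 2, 12 without oil 3, 92 without Brd4 LSECKO 1 and 79 without Brd4 LSECKO 3. The stellate count was 0 without oil 1, 4 without oil 2, 0 without oil 3, 20 without Brd4 LSECKO 1, 314 without Brd4 LSECKO 2 and 7 without Brd4 LSECKO 3. Of the 124 stellate genes 70 were higher and 54 lower in Brd4 LSECKO. Matrix genes, picked with their values known, went both ways. Higher were Ltbp2 (3.02 ± 0.47 (SE)), Mmp2 (2.15 ± 0.33) and Lum (1.78 ± 0.26), and lower were Fbln2 (-1.87 ± 0.37) and Col18a1 (-1.69 ± 0.29). The monocyte/macrophage count was 0 without oil 1, oil 2, Brd4 LSECKO 2 or Brd4 LSECKO 3 and 36 without Brd4 LSECKO 1. By DESeq2 and with the replicate block the counts were 560 and 487 in endothelial, 192 and 281 in Kupffer, 301 and 483 in stellate and 135 and 104 in monocyte/macrophage cells. With no filter they were 733, 423, 739 and 283 in the same order, and 1056 in T cells. Leiden resolution 0.5 gave 32 in Kupffer and 1 in monocyte/macrophage cells. Without the 2 libraries Kupffer cells gave 309, stellate cells 627 and monocyte/macrophage cells 0. Thinned, endothelial cells gave 160, Kupffer cells 105 and monocyte/macrophage cells 76. The 6 libraries alone gave 275, 204 and 99 in Kupffer, stellate and monocyte/macrophage cells, and doublets kept gave 207 in stellate cells. In endothelial cells Selp (2.58 ± 0.24), Esm1 (2.87 ± 0.29), Edn1 (2.19 ± 0.26) and Vwf (1.87 ± 0.28) were higher than in oil (adjusted p of 0.0080 at most), as they were in CCl4 fl/fl. These 4 were also picked with their values known, and they lead clusters whose part of the class differs: cluster 5 (Edn1, Selp and Vwf) held 6.77% ± 2.33 (SD) of it in Brd4 LSECKO against 1.85% ± 0.239 in oil, and cluster 6 (Esm1) 16.9% ± 7.57 against 3.62% ± 2.54. In hepatocytes, which lay mostly in cluster 33 in CCl4 fl/fl and in cluster 12 in Brd4 LSECKO and oil, the pericentral list lay above oil in Brd4 LSECKO (median log2 fold change 0.48, camera p = 2.6e-05, and p = 0.058 with an estimated correlation), which less loss alone would not give. The periportal list lay lower in CCl4 fl/fl against oil (median -0.83, 5 of 12 genes fell, p = 2.1e-05, and p = 0.080 with an estimated correlation), and its median in Brd4 LSECKO against oil was -0.18 (p = 0.23).

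Some values of the Brd4 LSECKO libraries lay away from those of oil. The unnamed clusters 14 and 21 held 3.52% and 5.5% of cells in Brd4 LSECKO against 0.812% and 1.5% in oil. In Kupffer cells 106 genes were higher and 56 lower than in oil. Among them, picked with their values known, Cx3cr1 was higher (log2 fold change 2.28 ± 0.30 (SE)), and Cd163 (-2.04 ± 0.21) and Timd4 (-1.55 ± 0.32) were lower. Many of the higher genes encode ribosomal proteins, such as Rps18 (1.34 ± 0.21), Rpl15 (1.30 ± 0.21) and Rpl32 (1.23 ± 0.20). What lies behind that shift was not tested. Many other values lay near those of oil, which could mean that these livers had been given no CCl4. The T cells argue against it: the covariance over genes of the 2 T cell effects against oil exceeded the value simulated for unchanged groups sharing the oil libraries (0.0329 ± 0.0013) by 0.2396, although a difference in handling between the oil libraries and both other groups, for which the labels give no batch, would also raise it. Less loss of pericentral hepatocyte transcripts, where CCl4 is activated, would point to milder injury in Brd4 LSECKO livers. The median log2 fold change of that list in hepatocytes was 0.8481 against CCl4 fl/fl (camera p = 0.0065, and p = 0.18 with an estimated correlation), but the list had no call in CCl4 fl/fl against oil (median -0.35, p = 0.72) and the periportal list lay higher too (median 0.92, p = 1.5e-06, and p = 0.055 with an estimated correlation), so milder injury and other causes cannot be told apart with these lists. An effect of endothelial Brd4 on inflammation, which the design names, stays open, as does one of tamoxifen or the recombinase.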
